A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

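Chromatin immunoprecipitation with antibodies to V5 or HA was followed by sequencing in 6 libraries of Saccharomyces cerevisiae, 1 per group: H3-V5, H3-HA, H2A.Z-V5 and H2A.Z-HA from cells in G1, and H3-V5 and H2A.Z-V5 from log phase. The treatment text gives alpha factor for 4 h for all 6, and log phase was taken from the sample names and sources. Per the labels, cells grew in rich medium at 30 °C, and chromatin was cut by sonication and micrococcal nuclease. Per the submitters' processing notes, reads were aligned with BWA 0.6.1 to genome build R64. The deposited files give, for each gene, a signal at each position around a reference point that is not stated, and the authors divided the values so that the mean of each table is 1. The values were tested on the files: they are whole multiples of 1 step per library, within 0.01 of a step, and the first position has the whole steps that a 50-position running mean gives at an edge. They were read as stacked 10-bp marks. No test of the mark length is given here, and all mark counts, depths and intervals on marks depend on it. From the step, the marks per bp and per window were recovered. Whether a mark stands for 1 fragment is not stated, so the intervals on marks cover counting error only. On simulated tables of 200 rows, the recovery gave a Pearson's r of 0.995 with the true marks and a median error of 0.368%. The simulation used the same mark length and so does not test it.

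The reference point was compared with annotated start codons. In 2473 of 2518 neighbouring pairs the rows of both genes lined up with a mean absolute difference of signal under 0.01, and in 1165 divergent pairs the distance between reference points exceeded that between start codons by a median of 19 bp (quartiles -23 and 56). Windows were therefore set on the reference point in the files, where start codons had been planned. The table mean of the authors replaced the planned scaling to the nuclear genome without the ribosomal DNA, which the files do not cover. The planned windows at gene ends, and those on transfer RNA genes, small nucleolar RNA genes, centromere DNA, replication origins, long terminal repeats, silent mating loci, ribosomal DNA and mitochondrial DNA, are not in the files and were left out.

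The promoter window ran from -400 to +200 bp and the body window from +500 to +1000 bp of genes of at least 1000 bp. The body window had been planned to run to the stop codon, but the rows end at +1000 bp. The ratio of mean signals was taken on the log2 scale after adding 0.05 to each. Log2 values, counts and ranks of genes use this ratio. Folds and ratios of single genes with their intervals are of the signals without the addition. They can therefore be larger than the log2 gives, and in another order, most at low signal. Left out were 26 rows identical to that of another gene and 3 promoters with a mean signal under 0.2 over the 6 libraries, which left 5089 promoters and 3228 bodies. A promoter counted as higher or lower at 1.5-fold, log2 0.585. With no replicates, no test was made, and ratios of single windows have a 95% exact binomial interval on the marks of both libraries. Intervals on shares of genes are exact binomial with genes as units, and those on medians are bootstraps over genes. Genes are not independent, and many promoter windows overlap, so these intervals only describe these libraries. For the difference of 2 log2 ratios no interval was computed. On simulated libraries with the measured depths, 99% of 100 genes set at 2-fold and all 100 set at 4-fold were recovered in H2A.Z over H3 in log phase, and all at both sizes in the 6 other ratios. Counting error alone called 1 of 4906 unchanged genes in H2A.Z-V5 G1 over log and none in the others.

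Comparisons, windows, thresholds, gene lists and the rule for named genes were fixed before the data were examined, apart from the changes to windows and scaling given above. The 16 lists were ribosomal protein, ribosome biogenesis, pheromone-induced, a-specific and alpha-specific mating type, G1/S, G2/M, M/G1, histone, glycolysis, galactose, phosphate, heat shock and stress, glucose-repressed, meiosis and sporulation, and strain marker and tag loci. The ribosomal protein list was built by a name pattern that also took RPP1, which encodes a subunit of RNase P, and was kept as fixed. Without RPP1, chosen after seeing the data, each of its medians that was recomputed stayed on the same side of 1.5-fold. The median log2 of a list is given, for some lists with its percentile among 10000 random lists of the same size, matched on signal in 10 strata, which describes these libraries and is not a test across samples. Where no percentile is given, a median can be ordinary for the signal of its list. Named genes are, per comparison, the 10 highest and 10 lowest promoter ratios among genes with a symbol, past the signal filter, outside repeat families and over 10 kb from chromosome ends, with the same sign in both parts of the window. By name stem, the repeat families include ribosomal protein and histone genes, so a list member can lie beyond the 10 named. A promoter shared by 2 such genes counts a single time, with both named. The highest and lowest members of each list described were named too, and all members of the strain marker list.

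Other settings chosen in advance were scaling to the median promoter, a pseudocount of 0.5, no signal filter, promoter windows of -500 to 0 and -150 to +150 bp, promoters that overlap no other, a 2-fold threshold, and a limit of 10 kb for chromosome ends. Added after seeing the data were thinning of the recovered marks to the shallowest library, exchange of the names of the libraries labelled G1 H3-HA and G1 H2A.Z-V5, and leaving out these libraries. The exchange was also applied to gene lists, named genes and the share of genes with the higher ratio at the promoter. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.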

Results

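Old and new histones were mapped along the genome of budding yeast (Saccharomyces cerevisiae, strain background S288C) by chromatin immunoprecipitation and sequencing. The strains use recombination-induced tag exchange (RITE), in which a recombinase replaces the tag on a histone gene, so that protein made before the switch carries one tag and protein made after it another. By the series design the V5 tag marks old protein and the HA tag new protein. Old and new protein were thus pulled down with different antibodies. A ratio of HA to V5 cannot part the age of the protein from the antibody, so only relative differences along the genome were read. No input library was available. The histones were H3, a core part of every nucleosome, and H2A.Z, the variant of H2A encoded by HTZ1. There were 6 libraries, 1 per group, with no replicates. The libraries labelled G1 H3-V5, G1 H3-HA, G1 H2A.Z-V5 and G1 H2A.Z-HA came from cells held in G1 with the mating pheromone alpha factor for 4 h, and those labelled log H3-V5 and log H2A.Z-V5 from log phase. The treatment text names alpha factor for the log-phase samples too, so that these cells were growing rests on the label alone. No difference below could be set against a spread between replicates, so every difference is between libraries, and genes are named by the size of the ratio. Each library covered the same genes from -1000 to +1000 bp of a reference point. The depth, as 10-bp marks per bp recovered from the steps in the values, was 1.04 for G1 H3-V5, 0.8 for G1 H3-HA, 0.685 for G1 H2A.Z-V5, 0.267 for G1 H2A.Z-HA, 0.525 for log H3-V5 and 0.398 for log H2A.Z-V5. The median promoter window held between 164 marks in the library labelled G1 H2A.Z-HA and 708.5 in that labelled G1 H3-HA.

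All 6 libraries showed phased nucleosomes with a gap upstream of genes. The first nucleosome stood highest in the library labelled G1 H3-HA, where the mean signal peaked at 4.37 times the table mean, and next in log H2A.Z-V5 at 3.47. The peak was 2.12 in G1 H2A.Z-HA, 1.93 in log H3-V5 and 1.55 in both the library labelled G1 H2A.Z-V5 and G1 H3-V5. The peak over the mean of positions +500 to +1000 was 7.14 in the library labelled G1 H3-HA and 4.27 in log H2A.Z-V5, against 2.2 in G1 H2A.Z-HA, 1.83 in log H3-V5, 1.43 in the library labelled G1 H2A.Z-V5 and 1.35 in G1 H3-V5. The upstream gap had its lowest point between -121 and -116 bp in every library. The peak of the first nucleosome lay 1 to 4 bp downstream of the reference point in every library. The promoter window, -400 to +200 bp, therefore includes this nucleosome, and promoter ratios depend on it.

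**Figure D1:**
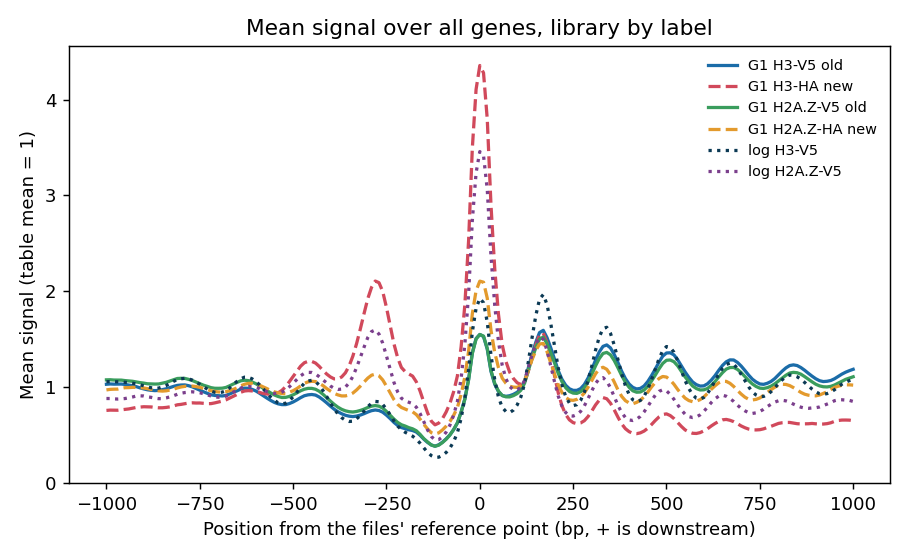
Mean signal over all genes (y axis, in multiples of the table mean) against position from the reference point in the files (x axis, bp), one line per library by its label. The lines labelled G1 H3-HA and log H2A.Z-V5 peak at 4.37 and 3.47, and the others between 1.55 and 2.12.

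Genes often deleted or altered in laboratory strains were read first, as a check of the labels. MET17, the O-acetylhomoserine sulfhydrylase gene used as a selection marker (R64 chromosome XII, 732542 to 733876), had a mean signal from 0 to +1000 bp of 1.05 in G1 H3-V5, 1.1 in the library labelled G1 H2A.Z-V5 and 1.28 in log H3-V5. It was 0.00375 in the library labelled G1 H3-HA, from 3 marks where a signal of 1 would give 801, and no mark was found in G1 H2A.Z-HA or log H2A.Z-V5, which allows a signal of up to 0.0112 and 0.00753. HHT1 and HHF1, a divergent gene pair on chromosome II encoding H3 and H4, split the libraries the other way, but only in the window from -1000 to -401 bp. From 0 to +1000 bp both had signal in every library, 0.537 to 1.49 at HHT1 and 0.713 to 1.08 at HHF1. Between -1000 and -401 bp of HHT1 there were no marks in G1 H3-V5 or the library labelled G1 H2A.Z-V5 and 1 mark in log H3-V5, against 98 in the library labelled G1 H3-HA, 112 in G1 H2A.Z-HA and 104 in log H2A.Z-V5. For HHF1 the same window held 0 marks in the first 3 of these libraries and 93, 79 and 62 in the others. These loci therefore grouped the library labelled G1 H3-HA with the H2A.Z libraries and that labelled G1 H2A.Z-V5 with the H3 libraries, against the labels of both. Each direction drawn below from either library depends on a label that these loci contradict. Other loci on the marker list did not part the libraries in this way. URA3 had a signal from 0 to +1000 bp of 0.0446 to 0.0884 in all 6 libraries, and TRP1 of 0.151 to 0.34. HIS3, LEU2, LYS2, ADE2, CAN1, LYP1, BAR1, HHT2, HHF2 and HTZ1 had marks in every library, with the lowest signal, 0.0932, at BAR1 in the library labelled G1 H3-HA.

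**Figure D2:**
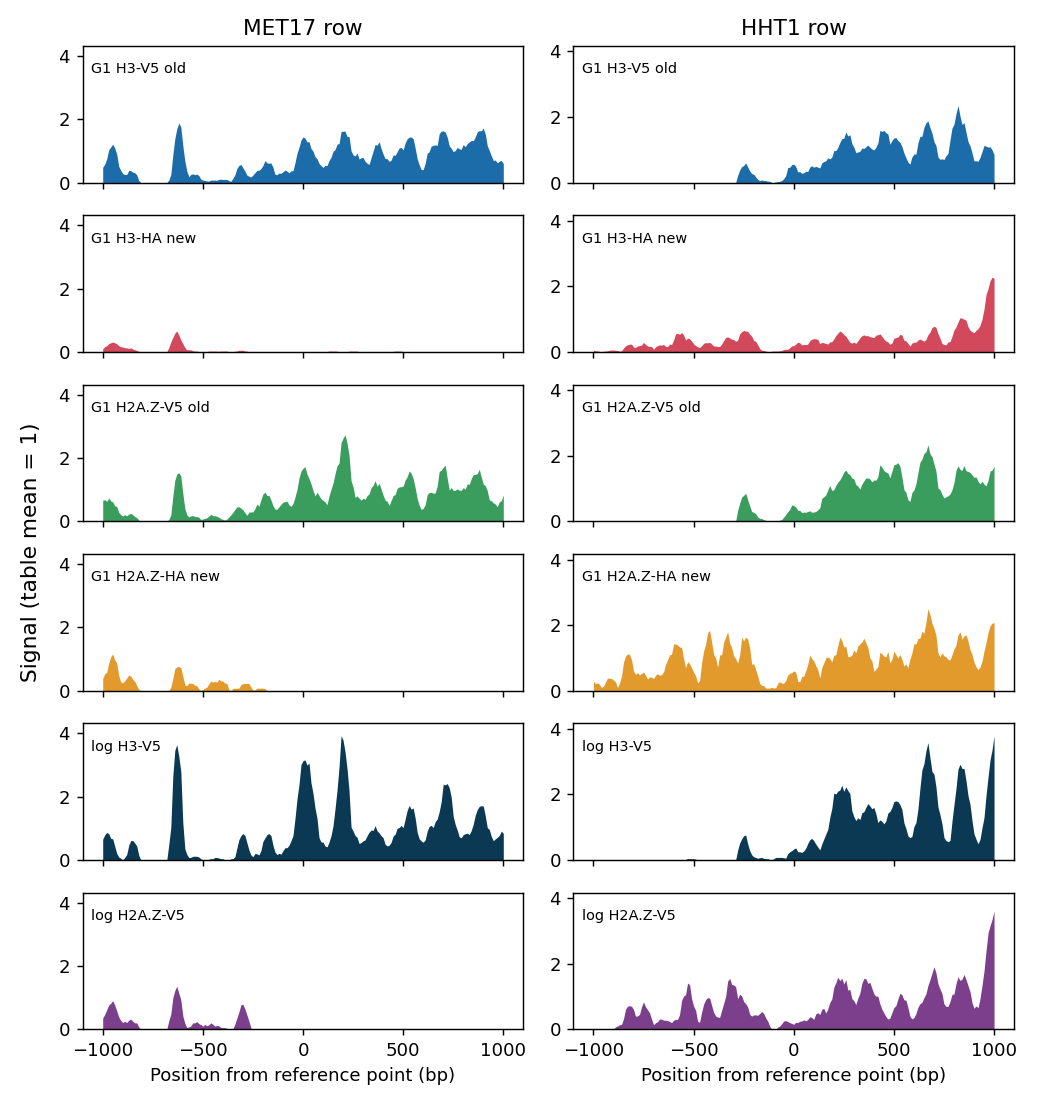
Signal (y axis, in multiples of the table mean) along the MET17 row (left) and the HHT1 row (right) against position from the reference point (x axis, bp), one panel per library by its label. MET17 signal downstream of 0 averages 1.05 to 1.28 in 3 libraries and rests on 0 to 3 marks in each of the others, and the HHT1 row upstream of -401 holds 98 to 112 marks in the latter and 0 or 1 in the former.

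The log-phase libraries, whose labels these loci do not contradict, gave the reference pattern of H2A.Z over H3. H2A.Z signal was concentrated at promoters. Of 3228 genes with both windows, 2973 (92.1%, exact binomial interval 91.1 to 93) had a higher ratio in the promoter, -400 to +200 bp, than in the body, +500 to +1000 bp. With the promoter set to -150 to +150 bp the share was 89.2%, and with -500 to 0 bp it was 94.4%. The median log2 ratio was 0.42 over 5089 promoters (quartiles -0.03 and 0.81) and -0.52 over gene bodies, and 2017 promoters were at least 1.5-fold higher in log H2A.Z-V5 and 334 at least 1.5-fold lower. The highest was UBP11, a ubiquitin protease gene, at 7.43-fold (6.27 to 8.83), followed by the cohesin gene SMC1 at 6.98-fold (6.04 to 8.12) and the shared promoter of DAL3 and MGA2 at 5.9-fold (5.08 to 6.88). POS5, SRS2, MMS1, SHS1 with GCS1, SNC1 with GIP4, COY1 and NOP8 with CTR9 lay between 5.98 and 4.74-fold. Under the rule for named genes, which leaves out ribosomal protein genes, the lowest after MET17 was STM1, at a ratio of 0.251 (0.191 to 0.322), then ZRT2, ADE3, HIP1, SSA3, SAM1, FKS1, EPL1 and HIS3 with MRM1, at 0.378 to 0.442. Of these 10, MET17, STM1, ZRT2, SAM1 and FKS1 lie on chromosome XII, where the median gene signal was 1.22 in log H3-V5 and 0.985 in log H2A.Z-V5.

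Ribosomal protein genes stood apart in the log-phase pattern: 76 of 138 promoters were at least 1.5-fold lower and 2 higher, with a median log2 of -0.61, under all 10000 random lists matched on signal (percentile 0). RPS25B, at log2 -1.34, and RPL34B, at -1.32, were the lowest, and RPS14B, at 0.92, the highest. The name pattern of this list also took RPP1, a gene for a subunit of RNase P, and without RPP1 1 of 137 was higher. Ribosome biogenesis promoters had a median of 0.58 (percentile 92.3), with 49 of 99 higher and 3 lower, NOP8 at 2.15 and RLP24 at -0.79. Glycolysis genes had a median of -0.01, with 2 of 19 higher and 1 lower. When each library was scaled to its median promoter, which moved the median log2 of all promoters from 0.42 to -0.01, 756 promoters were higher and 1005 lower, ribosomal protein promoters had a median of -1.01, and ribosome biogenesis promoters one of 0.16, with 20 of 99 higher and 11 lower.

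The libraries labelled G1 H3-V5 and log H3-V5, which the loci above do not part, compared old H3 in arrested cells with H3-V5 in cells labelled as in log phase. H3 signal was lower in G1 at the promoters of pheromone-induced and a-specific mating genes, of glycolysis genes and of histone genes. Percentiles among signal-matched lists are not given here for the a-specific, glycolysis and histone medians. Of 36 pheromone-induced genes, 25 were at least 1.5-fold lower and none higher, with a median log2 of -0.86 (percentile 0), from SCW10, a cell wall glucanase gene, at -1.90 and PRM8 at -1.75 to KAR5 at -0.05. Of 7 a-specific genes, which only cells of the a mating type use, 6 were lower, with a median of -1.10, among them ASG7 at -1.66 and the pheromone gene MFA1 at -1.54, with STE6 highest at -0.29. The 5 genes specific to the alpha mating type all lay within 1.5-fold, with a median of -0.06. Glycolysis genes had a median of -0.62, with 12 of 19 lower, led by the pyruvate decarboxylase gene PDC1 at -2.43 and the enolase gene ENO2 at -1.14, and HXK1 highest at 0.20. Histone genes had a median of -0.66, with 6 of 11 lower, HTA1 at -1.30 and HTB1 at -1.29, and 8 of 41 heat shock and stress genes were lower, with a median of -0.30 (percentile 0), SSA1 at -1.10 and SSE1 highest at 0.27.

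Over all genes this H3 comparison was centred near 0, with a median log2 of 0.00 for promoters (quartiles -0.27 and 0.23) and 0.24 for bodies, and 180 promoters were at least 1.5-fold higher and 487 lower in G1 H3-V5. The lowest was HSP150, a cell wall protein gene, at a ratio of 0.124 (0.102 to 0.15), with PDC1 at 0.156 (0.128 to 0.19) and the cell wall gene SED1 at 0.181 (0.139 to 0.231). PMU1, SPC25 with ISC1, HOS2 with IME4, SCW10, PRY2, APC9 and NCW2 followed at 0.22 to 0.273. The highest was GIT1, which encodes a glycerophosphoinositol permease, at 2.46-fold (2.12 to 2.88), and SRO77, CPT1, HIM1, SPS2, BRE5, the transcription factor gene SWI5, HOS3, KAP114 with ANK1 and NFT1 lay between 2.14 and 1.86-fold. SWI5 was also the highest of the G2/M list, whose median was 0.25 (percentile 99.5) with 3 of 23 higher. Meiosis and sporulation genes had a median of 0.25 (percentile 100), with 3 of 39 higher and 2 lower. The median was 0.13 for ribosome biogenesis, -0.03 for ribosomal protein, -0.06 for G1/S, -0.10 for M/G1, 0.08 for galactose, -0.02 for phosphate, -0.21 for glucose-repressed and -0.11 for strain marker and tag loci. In gene bodies the median was -0.46 for pheromone-induced, -0.49 for glycolysis, -0.48 for ribosomal protein (14 bodies, 5 lower), -0.27 for glucose-repressed, -0.01 for heat shock and stress and 0.43 for ribosome biogenesis genes, against 0.24 for all genes. Scaling to the median promoter gave 194 higher and 488 lower, and each list median kept its sign. With the promoter window set to -150 to +150 bp, 428 were higher and 460 lower.

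The design sets new over old H2A.Z against new over old H3 in G1. This difference of the HA over V5 log2 ratios of both histones takes the same value for every gene when the names of the libraries in doubt are exchanged, since both of them enter it with the same sign. It would not keep its value under other errors of naming, such as in the tags, which were not checked. Among the lists it was highest at pheromone-induced genes and ribosomal protein genes. Of 36 pheromone-induced promoters, 32 were at least 1.5-fold higher and none lower, with a median log2 of 1.53 (percentile 100), led by PRM1, a gene for a membrane protein of mating cells, with its neighbour ERG24 at 2.61 and by the alpha factor receptor gene STE2 at 2.49, with KAR3 lowest at -0.31. Of 138 ribosomal protein promoters, 120 were higher and 5 lower, with a median of 1.33 (percentile 100), RPL31A at 2.57 and RPL13B at 2.37 the highest and RPL15B lowest at -0.97. Without RPP1, 4 were lower. The a-specific list had a median of 1.02 with 5 of 7 higher, which signal-matched random lists often reach (percentile 73), and the alpha-specific list one of -0.04 with 1 of 5 higher and 2 lower. Histone genes had a median of -0.67 (percentile 0.04), with HHO1 lowest at -1.10, HTZ1 at -1.06, and HHT1, whose row lacked upstream marks in 3 libraries, highest at 1.29. Promoter signal in the library labelled G1 H3-HA was low at PRM1 (0.0464) and STE2 (0.0735), against 0.806 and 1.23 in G1 H2A.Z-HA. G1 H2A.Z-HA was the shallowest library. Its mean profile was flatter, with a peak over body of 2.2 against 7.14 in the library labelled G1 H3-HA. How far this sets the difference was not tested.

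Across all 5089 promoters the median of this difference was -0.49, with 516 higher and 2171 lower, and in gene bodies it was 1.26, with 2639 higher and 53 lower. HSP150 at 2.40, FUS1 at 2.31, HPF1, CCW12, PMU1, SIM1, GIC2 and ARB1 at 2.09 completed the highest 10 under the rule for named genes, which leaves out ribosomal protein genes such as RPL31A. The lowest was the promoter of SMX2 and LPD1 at -2.06, then IMP21 with RRD1 at -2.01, the alpha factor gene MF(ALPHA)1 at -1.90, NAR1 with LAP3, POC4, PDR8, HAP5 with SNX3, SHR3 with NOP6, MDJ2 and SYC1 at -1.68. Scaling each library to its median promoter moved the median from -0.49 to 0.04 and gave 1027 higher and 355 lower. Under it the pheromone-induced median was 1.92, the ribosomal protein median 1.74 and the histone median -0.17, while ribosome biogenesis went from -0.56 to -0.01.

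New over old H3 in G1, as labelled, was the ratio of the library labelled G1 H3-HA to G1 H3-V5. These libraries differ in antibody as well as in the labelled age of the protein. The library labelled G1 H3-HA was higher at promoters and lower in bodies: the median log2 was 0.74 over promoters and -1.5 over bodies, 3137 of 3228 genes (97.2%, 96.6 to 97.7) had the higher ratio at the promoter, and 2976 promoters were at least 1.5-fold higher and 524 lower. SYC1 was highest at 6.6-fold (5.95 to 7.33), with MBA1 and PCH2, PXR1, DAL3 and MGA2, POS5, MF(ALPHA)1, FIS1 and EFM4, ALG3, DCP1, and MRPL11 and ACK1 at 6.15 to 5.1-fold. After MET17, the lowest under the rule for named genes were ADY3 at 0.205 (0.172 to 0.244), SAT4, RPO21, which encodes the largest subunit of RNA polymerase II, GFA1, SSD1, SAC7, AFR1, SIM1 and PGU1, with signal ratios of 0.183 to 0.242. Ribosomal protein promoters had a median of -1.11 (percentile 0), with 109 of 138 lower, RPL37A at -1.95 lowest and RPL18B highest at 1.29. Of 36 pheromone-induced promoters 31 were lower, with a median of -1.20 (percentile 0.02), from PRM10 at -1.88 to KAR3 at 0.67. Ribosome biogenesis promoters had a median of 1.13 with 87 of 99 higher, ENP2 at 2.17 and UTP22 at -0.58, and G1/S promoters one of 1.07 with 31 of 47 higher, PCL1 at 2.05 and CRH1 at -1.42. Scaled to the median promoter, 799 were higher and 1263 lower, the histone list went from 0.69 to -0.01, and the ribosome biogenesis and G1/S medians went to 0.37, with 28 higher and 4 lower, and 0.30, with 10 higher and 10 lower. With the names of both doubted libraries exchanged, chosen after seeing the data, 522 promoters were higher and 96 lower, and 195 of the 522 were among the 2976. Then 67.6% of genes had the higher ratio at the promoter, and the medians were 0.08 for ribosomal protein, 0.66 for pheromone-induced, -0.25 for ribosome biogenesis and 0.02 for G1/S promoters. In place of SYC1 and ADY3, the highest named gene was then SED1 at 4.07-fold and the lowest SAP155 at a ratio of 0.525.

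New over old H2A.Z in G1, as labelled, was the ratio of G1 H2A.Z-HA to the library labelled G1 H2A.Z-V5. Promoters were mostly higher in G1 H2A.Z-HA, with a median log2 of 0.24 and 794 at least 1.5-fold higher against 36 lower, while bodies had a median of -0.22. The highest were RRP6, an exosome nuclease gene, at 5.11-fold (4.26 to 6.16), TFC3 at 4.76-fold (3.97 to 5.75), OSH7 at 4.09-fold (3.38 to 4.93) and STE2 at 3.98-fold (3.17 to 5.01), with ENP2, POS5, KRE33, HSP150, DSE1 and AVT1 at 2.98 to 2.79-fold. RRP6, TFC3, OSH7 and AVT1 carry the number 1, counted from the centromere, in their systematic names. The lowest after MET17 were ACS2, an acetyl-CoA synthetase gene, at 0.404 (0.312 to 0.52), UPS2, MIM2 with ICT1, ROX1, NHA1, CUP9, ECM22, PHO84 and ROQ1 at up to 0.58. MET17, ACS2, UPS2, MIM2, NHA1 and ECM22 lie on chromosome XII, whose median gene signal was 1.02 in G1 H2A.Z-HA and 1.14 in the library labelled G1 H2A.Z-V5. Ribosome biogenesis promoters had a median of 0.54 (percentile 100), with 45 of 99 higher and none lower, ENP2 at 1.48, SSF1 at 1.39 and CBF5 lowest at -0.20. Heat shock and stress promoters had a median of -0.05 (percentile 0), with 1 of 41 higher, ALD4 at 0.76 and SSA3 lowest at -0.46. Scaling to the median promoter moved the median to 0.02 and gave 265 higher and 152 lower, with 17 of 99 ribosome biogenesis promoters higher and a median of 0.32 for that list. With the names exchanged, 640 were higher and 2305 lower, and 48 of the 640 were among the 794. Ribosome biogenesis promoters then had a median of -0.78 with none higher and 73 lower, heat shock and stress promoters one of 0.01, and 4.68% of genes had the higher ratio at the promoter, against 89% as labelled. Across genes, the new over old promoter ratios of both histones, as labelled, had Pearson's r of 0.551 and Spearman's rho of 0.619 at promoters and 0.224 and 0.0988 in bodies. After the exchange of names these were 0.449 and 0.42 at promoters and -0.0394 and -0.163 in bodies. Genes are not independent replicates here.

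H2A.Z-V5 in G1 against log phase was the ratio of the library labelled G1 H2A.Z-V5 to log H2A.Z-V5. Ribosomal protein promoters were higher in the library labelled G1 H2A.Z-V5, with a median log2 of 0.70 (percentile 100) and 88 of 138 at least 1.5-fold higher, RPL31B at 1.58. The 1 lower was RPP1 at -0.60, and the lowest gene of a ribosomal protein was RPL15B at -0.35. Ribosome biogenesis promoters had a median of -0.70 (percentile 0), with 54 of 99 lower, RRP15 at -2.18, ENP2 at -2.11 and DBP2 highest at 0.63. Over all promoters the median was -0.41, with 438 higher and 2025 lower, and over bodies it was 0.56. Under the rule for named genes, which leaves out ribosomal protein genes, MET17 was highest, with 11.2-fold (6.94 to 20.3) from 16 marks in log H2A.Z-V5, then ACS2, STM1, PYC2, the phosphate transporter gene PHO84, RNH203, PHO87, ENT5, RBA50 and ADE3 at 3.82 to 2.61-fold. MET17 is the locus without marks in log H2A.Z-V5 downstream of 0. ACS2, STM1 and RNH203 lie beside the ribosomal DNA on chromosome XII, where gene bodies within 50 kb had a median log2 of 0.55 over the other chromosomes in the library labelled G1 H2A.Z-V5 and 0.07 in log H2A.Z-V5. SMC1 and UBP11 were lowest, both at 0.14 (0.122 to 0.159 and 0.121 to 0.163), then STT3 with PIB2, SSK22 with SOL2, SNC1 with GIP4, SRS2, VMA1, DAL3 with MGA2, CRP1, and MRPL11 with ACK1 at 0.157 to 0.206. Scaled to the median promoter, 1016 were higher and 922 lower, with medians of 1.08 for ribosomal protein genes, 128 higher, and -0.29 for ribosome biogenesis genes, 26 lower. With the names exchanged, 1152 were higher and 549 lower, all 36 pheromone-induced promoters were lower with a median of -1.97, and the medians were -0.49 for ribosomal protein and 0.62 for ribosome biogenesis promoters. Without the doubted libraries, G1 H2A.Z-HA over log H2A.Z-V5 gave 447 higher and 873 lower.

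H2A.Z over H3 in G1 was read for each tag, as labelled. For V5, the library labelled G1 H2A.Z-V5 over G1 H3-V5 had a median promoter log2 of -0.02, with 522 higher and 96 lower, and 67.6% of genes (65.9 to 69.2) had the higher ratio at the promoter, against 92.1% in log phase. Glycolysis promoters had a median of 0.93 (percentile 100) with 16 of 19 higher, PDC1 at 1.29, CDC19 at 1.25 and PDC5 lowest at -0.21. The a-specific genes had a median of 0.95 with 6 of 7 higher, histone genes one of 0.83 with 8 of 11 higher, HTA1 at 1.64 and HHT2 at 1.41, and pheromone-induced genes one of 0.66 with 19 of 36 higher, PRM3 at 1.35 and KAR3 lowest at -0.14. The highest single genes under the rule for named genes, which leaves out histone genes, were SED1 at 4.07-fold (3.18 to 5.29), PRY2, NCW2, ECL1, TYE7, a glycolysis activator gene, ERG27, the drug pump gene PDR5, PMU1, PMP1 and PRM3 at 2.88-fold. The lowest were SAP155 at 0.525 (0.453 to 0.608), MLP2, NDD1 with NUD1, MPS1, SLM1, RIX7 with IRC19, TFG1 with TYS1, UFD4 with MRT4, GRR1 and NUP85 with URB2, none under 0.518. The G2/M list had a median of -0.34 (percentile 0) with 1 of 23 lower, NUD1 at -0.76. All these list medians kept their sign when scaled to the median promoter. With the names exchanged, 97.2% of genes had the higher ratio at the promoter, and the medians were -0.12 for glycolysis, -0.66 for a-specific, 0.69 for histone, -1.20 for pheromone-induced and 0.37 for G2/M genes.

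For HA, G1 H2A.Z-HA over the library labelled G1 H3-HA had a median of -0.52 over promoters and 1.01 over bodies, with 640 promoters higher and 2305 lower, and 4.68% of genes (3.98 to 5.46) had the higher ratio at the promoter. Pheromone-induced promoters had a median of 2.12 (percentile 100) with 35 of 36 higher, STE2 at 3.37, PRM1 at 3.15 and KAR3 at -0.45. Ribosomal protein promoters had a median of 1.5 with 122 of 138 higher, RPL31A at 2.39, and 1 lower, RPP1 at -0.99, with RPS21A next at -0.54. The 7 a-specific genes were all higher with a median of 1.97, and 15 of 19 glycolysis genes were higher with a median of 1.21. Ranked by log2, HSP150 was highest at 3.71, a signal ratio of 20.1-fold (14.4 to 28.3). PMU1 followed at 3.56, a signal ratio of 17.3-fold (12.6 to 23.8), then STE2, PRM1 with ERG24, SCW10, CCW12, PRM4, ZEO1, HPF1 and PDR5, each at least 8.3-fold in signal. ERG12, of the mevalonate pathway, was lowest at 0.325 (0.281 to 0.375), with IWR1, MGL2, MRPL11 with ACK1, MBA1 with PCH2, MF(ALPHA)1, RFA2 with EMW1, TUB1, TFB2 and GCS1 with SHS1 up to 0.377. Scaled to the median promoter, 1123 were higher and 295 lower, with a pheromone-induced median of 2.47. With the names exchanged, 2976 promoters were higher and 524 lower for V5 and 794 and 36 for HA. For HA, 89% of genes then had the higher ratio at the promoter, and the medians were 0.26 for pheromone-induced, 0.28 for ribosomal protein, 0.40 for a-specific and 0.12 for glycolysis promoters. HSP150 then had 2.87-fold with HA, and RRP6 was the highest named gene at 5.11-fold. Without the doubted libraries, G1 H2A.Z-HA over G1 H3-V5 gave 1040 higher and 37 lower.

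**Figure D3:**
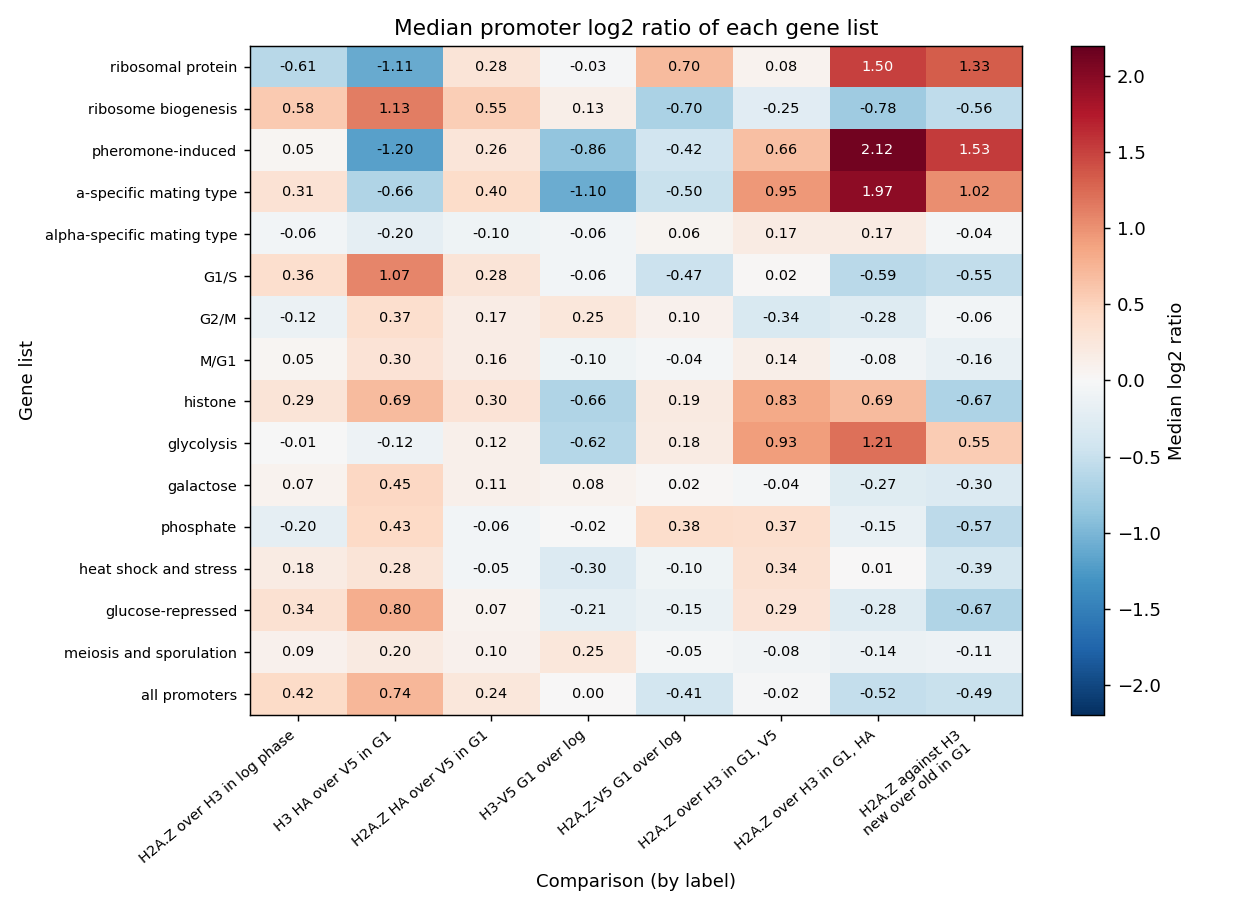
Median promoter log2 ratio (colour and printed value) of each gene list (rows) in each comparison by label (columns), with all promoters in the bottom row. Pheromone-induced genes run from -1.20 in the ratio labelled new over old H3 to 2.12 in H2A.Z over H3 with the HA tag, and scaling to the median promoter shifts the columns.

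Genes near chromosome ends were compared with the rest, by distance to the outermost annotated gene. In H3-V5 G1 over log, 31 of 127 promoters within 20 kb of an end were at least 1.5-fold higher and 7 lower (24.4%, 17.2 to 32.8), against 149 higher and 480 lower of 4962 elsewhere, and the median log2 near ends was 0.27. Within 10 kb, 22 of 51 were higher, with a median of 0.47. In H2A.Z over H3 in log phase the median was 0.45 within 20 kb, 0.42 elsewhere and 0.03 within 10 kb. Genes close to chromosome ends often belong to families with similar copies, so their reads are less certain.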

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

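All tests in this part were chosen after the result was seen. With the libraries taken by their labels, 6 gene lists of at least 5 members had medians of opposite sign for the histones H3 and H2A.Z under the same contrast, with the larger past 1.5-fold and the smaller at least 0.1 in log2. Lists with smaller opposite medians are not given here, and none of these differences was tested. In the ratio of HA to V5 in G1, the median log2 of H2A.Z minus that of H3 was 1.39 for ribosomal protein promoters, 1.46 for pheromone-induced promoters and 1.06 for a-specific promoters. In the ratio of G1 to log phase with V5, the H2A.Z median minus the H3 median was -0.83 for ribosome biogenesis promoters, 0.85 for histone promoters and 0.80 for glycolysis promoters. Scaled to the median promoter, 3 of the 6 no longer meet these limits: the H2A.Z median is 0.06 for ribosomal protein and 0.04 for pheromone-induced promoters in HA over V5, and -0.29 for ribosome biogenesis promoters in G1 over log. With the names of the libraries labelled G1 H3-HA and G1 H2A.Z-V5 exchanged, all 6 lists have medians of the same sign. In the order above, H3 and H2A.Z then give 0.08 and 1.5, 0.66 and 2.12, 0.95 and 1.97, 0.13 and 0.62, -0.66 and -0.47, and -0.62 and -0.74. The 6 lists were chosen for opposite signs as labelled, so their shared sign after the exchange is no support for it. Other lists went from the same sign to opposite signs. In HA over V5 these include G1/S, at 0.02 for H3 and -0.595 for H2A.Z, and glucose-repressed promoters, at 0.295 and -0.28.

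MET17, HHT1 and HHF1 split the libraries against their labels. The labelled histone as what sets the signal at MET17 is argued against by 0.00375 in the library labelled G1 H3-HA, where both other H3 libraries are above 1, and by 1.1 in that labelled G1 H2A.Z-V5, where the other H2A.Z libraries allow at most 0.0112. The labelled tag is argued against in log phase, where log H2A.Z-V5 allows at most 0.00753 and log H3-V5 has 1.28, but it stays open in G1, where both V5 libraries are at least 93.8 times above both HA libraries and the tag runs along with the split. A mixture of both strains is argued against by an upper limit of 1.63% for the share of the other strain in the libraries in doubt. An exchange of the names of the libraries labelled G1 H3-HA and G1 H2A.Z-V5, at a stage that stays open, remains a candidate explanation: over the whole tables the former correlates better with log H2A.Z-V5 than with log H3-V5, and the latter the other way round, and the smaller of the differences of r is 0.336. These loci and correlations were read for strain and histone, and the tag of each library was not checked.

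Genes near centromeres were higher in the library labelled G1 H2A.Z-HA than in the others. Even background of DNA not bound by the antibody is argued against by a median signal of 1.41 (bootstrap interval 1.14 to 1.59) over the 29 genes with the number 1 from a centromere in their systematic names, above the table mean of 1. Of these, QCR10 lies beyond OSH7, and without it the median is 1.42 (1.14 to 1.6). Extra copies of centromere DNA in the H2A.Z strain are argued against by 28 of these 29 genes being higher than in log H2A.Z-V5. New H2A.Z near centromeres in G1, and binding of the HA antibody to another protein there, were not tested and stay open in this single library.

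Genes around the ribosomal DNA on chromosome XII were higher in G1 H3-V5, the library labelled G1 H2A.Z-V5 and log H3-V5, the libraries with MET17 signal. For the library labelled G1 H2A.Z-V5 and log H3-V5, reads of the ribosomal DNA placed on neighbouring genes are argued against by medians over the other chromosomes of at least 0.342 in log2 for gene bodies 50 to 100 kb away (0.258 to 0.433, and 0.511 to 0.775 in log H3-V5). For G1 H3-V5 that median is 0.332 (-0.036 to 0.484), which leaves this explanation open. A duplicated segment with fixed ends stays open too: a fall from within 50 kb to 50 to 100 kb, with elevation left at 100 to 200 kb, lay beyond the bootstrap intervals in 1 of the 3 libraries. A difference between strains or cell populations in the DNA of this region was not tested and stays open.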

How the results depend on the processing

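The exchange of names, the omission of the libraries in doubt, the thinning of marks and the removal of RPP1 were chosen after seeing the data. No paired analysis was possible because each group has 1 library. Of the counts of promoters under the alternatives, 73 stayed within 1.5 times the count first given, 71 did not, and 6 are left as they are by the exchange. Values that a setting leaves unchanged by construction are not counted as stable here. Without the signal filter, which removes only 3 promoters, all 16 counts stayed within it. Of the percent values, 4 stayed within their exact binomial interval, 30 moved, and 9 were unchanged by construction. The percent of genes with the higher ratio at the promoter moved in all 7 ratios with the window at -150 to +150 bp and in 6 at -500 to 0 bp, where that of H3 HA over V5 stayed. In that order of windows, it was 89.2 and 94.4 in log phase, 95.8 and 97.3 in H3 HA over V5, 85.8 and 90.4 in H2A.Z HA over V5, and 62.2 and 72.4 in H2A.Z over H3 with V5. List medians past 1.5-fold, or at the extremes of the random lists, were recomputed under the settings for scaling, pseudocount, filter, window, overlap and exchange, and without RPP1 for ribosomal proteins: 240 values stayed on the same side of 1.5-fold, 65 crossed it, 12 reversed and 68 were unchanged by construction, where only a median past 1.5-fold could be counted as reversed. Of the values of named genes, 362 stayed within their counting interval (for the difference between the histones, on the same side of 1.5-fold), 327 moved and 51 reversed, all of these under the exchange. Another 312 were unchanged by construction, since dropping the filter or leaving out overlapping promoters alters no ratio of a single promoter and the exchange leaves 3 comparisons as they are. Of the reversed medians, 1 was that of the histone list in H3 HA over V5, -0.01 when scaled to the median promoter. The other 11 belong to the exchange. They were 0.08 for ribosomal protein, -0.25 for ribosome biogenesis, 0.66 for pheromone-induced and 0.95 for a-specific genes in H3 HA over V5, and -0.49 for ribosomal protein and 0.62 for ribosome biogenesis genes in H2A.Z-V5 G1 over log. In H2A.Z over H3 they were -1.20 for pheromone-induced, -0.66 for a-specific and -0.12 for glycolysis genes with V5, and 0.54 for ribosome biogenesis and 0.28 for G1/S genes with HA.

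Below, counts are promoters higher and lower, in that order, where both moved. Scaling to the median promoter gave 756 and 1005 for H2A.Z over H3 in log phase, 799 and 1263 for H3 HA over V5, 265 and 152 for H2A.Z HA over V5, 1016 and 922 for H2A.Z-V5 G1 over log, 1123 and 295 for H2A.Z over H3 with HA, and 1027 and 355 for the difference between the histones in new over old. It sets each library's median promoter to the same level, which by construction shifts the ratios of a comparison together.

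A pseudocount of 0.5, which by construction draws ratios toward 0, gave 1276 and 62 for H2A.Z over H3 in log phase, 206 lower for H3 HA over V5, 232 and 5 for H2A.Z HA over V5, 15 and 133 for H3-V5 G1 over log, 69 and 1348 for H2A.Z-V5 G1 over log, 121 and 0 for H2A.Z over H3 with V5, 374 higher with HA, and 250 and 1406 for the difference. The 2-fold threshold, stricter by construction, gave 797 and 49, 1780 and 292, 95 and 2, 12 and 112, 65 and 921, 107 and 0, 413 and 597, and 313 and 587, in the order log phase, H3 HA over V5, H2A.Z HA over V5, H3-V5 G1 over log, H2A.Z-V5 G1 over log, H2A.Z over H3 with V5, with HA, and the difference.

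With the window at -500 to 0 bp, 197 were lower in log phase and 282 higher in H3-V5 G1 over log. At -150 to +150 bp, 74 were lower in H2A.Z HA over V5, 428 higher in H3-V5 G1 over log and 206 lower in H2A.Z over H3 with V5. The cause was not tested. With only the 2959 promoters that overlap no other, fewer genes were counted: 984 higher in log phase, 1487 higher in H3 HA over V5, 323 and 23 in H2A.Z HA over V5, 269 lower in H3-V5 G1 over log, 907 lower in H2A.Z-V5 G1 over log, 326 and 37 in H2A.Z over H3 with V5, 1045 lower with HA, and 1104 lower for the difference.

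With marks thinned, 174 were lower in H2A.Z over H3 with V5, and the other 15 counts stayed within 1.5 times. With the names exchanged, the counts were 522 and 96 for H3 HA over V5, 2305 lower for H2A.Z HA over V5, 1152 and 549 for H2A.Z-V5 G1 over log, 2976 and 524 for H2A.Z over H3 with V5, and 36 lower with HA. Of the 438 promoters higher in H2A.Z-V5 G1 over log as labelled, 73 were also higher after the exchange. Without the libraries in doubt, G1 H2A.Z-HA had to stand in for H2A.Z-V5 in G1, so the tag and the age of the protein differ. Against log H2A.Z-V5, 873 were then lower. H2A.Z over H3 in G1, taken as G1 H2A.Z-HA over G1 H3-V5, gave 1040 and 37 in place of both tags. These are other comparisons, and 1 of their 6 counts, which the totals above include, stayed within 1.5 times. H3 HA over V5, H2A.Z HA over V5 and the difference need these libraries and have no such value.

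With the names exchanged, 60 values of named genes are unchanged by construction. Of the 100 others, 3 stayed, 46 moved and 51 reversed, with the exchanged log2 given after each gene. In H3 HA over V5 these were POS5 -0.26, ALG3 -0.22, MRPL11 -0.14, MET17 0.31, GFA1 0.30, SAC7 0.01, AFR1 0.61 and SIM1 0.16. In H2A.Z HA over V5 these were ENP2 -1.14, POS5 -1.18, KRE33 -1.0, DSE1 -0.97, MET17 0.68, UPS2 0.57, MIM2 0.99, ROX1 0.64, CUP9 1.18, ECM22 0.54 and ROQ1 0.55. In H2A.Z-V5 G1 over log these were MET17 -1.05, ENT5 -0.19, ADE3 -0.31, VMA1 0.01 and MRPL11 0.21. In H2A.Z over H3 with V5 these were SED1 -0.14, PRY2 -0.68, ECL1 -0.79, TYE7 -1.27, PDR5 -0.96, PMU1 -1.14, PMP1 -0.93, PRM3 -0.89, SAP155 0.61, MLP2 0.69, NDD1 1.48, MPS1 0.83, SLM1 0.43, RIX7 1.68, TFG1 0.86, UFD4 0.40 and NUP85 1.09. In H2A.Z over H3 with HA these were ERG12 0.49, IWR1 0.21, MGL2 0.29, MRPL11 0.97, MBA1 0.94, MF(ALPHA)1 0.46, RFA2 0.89, TUB1 0.77, TFB2 0.62 and GCS1 0.77.

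Within 10 kb of chromosome ends, the percent of promoters higher was 27.5 in log phase, 23.5 in H3 HA over V5, 43.1 in H3-V5 G1 over log, 0 in H2A.Z over H3 with V5, 39.2 with HA and 45.1 for the difference, of 51 promoters. With the names exchanged, it would be 0 in H3 HA over V5, 23.5 in H2A.Z over H3 with V5 and 17.6 with HA. The values for log phase, H3-V5 G1 over log and the difference would stay. A scaling that includes ribosomal and mitochondrial DNA was not run, since the files lack both. Depth limits the library labelled G1 H2A.Z-HA most, with a median of 164 marks per promoter.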

Other observations

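In log phase, H2A.Z over H3 in gene bodies also differed between gene groups. Against a median log2 of -0.52 over all 3228 bodies, meiosis and sporulation genes had a median of -0.05 (28 bodies, percentile 100), with SPR3 at 0.87, SSP1 at 0.80 and IME4 lowest at -0.90. Phosphate genes had a median of 0.04 (11 bodies, percentile 100), from PHO8 at -1.01 to PHM7 at 1.48. Glucose-repressed genes had a median of -0.32 (25 bodies, percentile 99.6), with YAT2 at 1.1, REG2 at 0.94 and HXT13 lowest at -1.13. Ribosomal protein genes with a body window had one of -0.87 (14 bodies, percentile 0.01).

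If the names of the libraries labelled G1 H3-HA and G1 H2A.Z-V5 were exchanged, which the differences of r of 0.336 and 0.447 make a candidate explanation, old H2A.Z in G1 may be low at pheromone-induced genes. The loci and these differences were read for strain and histone, and the tag was not checked. The library labelled G1 H3-HA could thus hold new H2A.Z instead. Each value below that changes with the exchange rests on this 1 library. In H2A.Z-V5 G1 over log, all 36 pheromone-induced promoters would then be at least 1.5-fold lower, with a median log2 of -1.97, and all 7 a-specific promoters, with one of -1.66, against 0.26 over all promoters. Part of this is shared by H3-V5, whose medians in G1 over log are -0.86 and -1.10 at the same promoters. Set against H3-V5 in G1, H2A.Z-V5 would have a median of -1.20 for pheromone-induced promoters (percentile 0.02) but one of -0.66 for a-specific promoters (percentile 62.6), which is not low for their signal. The pattern would not be one of all mating genes or of mating genes alone: in G1 over log the alpha-specific median would be -0.08, with 1 of 5 higher and 2 lower, that of glycolysis -0.74 with 11 of 19 lower, and that of ribosomal protein -0.49 with 61 of 138 lower. Ribosome biogenesis promoters would have a median of 0.62 with 56 of 99 higher. In H2A.Z HA over V5, 35 of the 36 pheromone-induced promoters would be higher, with a median of 2.12. This was read from the data that raised it, was not tested and is a hypothesis. Replicate H2A.Z-V5 and H3-V5 libraries from G1 and log phase, with the strain checked at MET17 and the tag checked separately, would test it.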
